A study of Mus musculus with 6 samples.

How the data were processed

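RNA sequencing of primary mouse fibroblasts was compared between 3 control libraries and 3 libraries of cells treated with CXCL3 for 48 h. Group and replicate number were taken from the sample labels. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase and made into Illumina libraries after a check of RNA quality. Whether the libraries keep strand is not given in the sources used here. The authors deposited 1 table of TPM for 51912 genes, with 1 column for each library and 0 columns of other samples. The submitters' processing notes name fastp, HISAT and RSEM and the genome build GRCm38.p5, without versions or order. The annotation release and any filter are not given in the sources used here. The columns of the rows used here sum to between 984281 and 986705 TPM.

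TPM is a share, so it keeps no library depth. The precision of a value was judged from the spread between the 3 libraries of a group, and no counting interval or floor is given. TPM of a gene also moves with every other gene's, and with how evenly transcripts of different length were sampled. Genes that share reads with close paralogs, pseudogenes or overlapping genes depend on how RSEM divided those reads, which holds for the mitochondrial genes mt-Atp8 and mt-Co1 and the nuclear pseudogene Gm28661 among those named.

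Gene identifiers were matched to GENCODE mouse release M21, an annotation of GRCm38, which gave a symbol for 51719 of the 51912 genes, the gene type, the position and the length and GC content of the longest transcript. Of the 13139 genes kept, 13114 (99.81%) had a length. Genes were kept with a TPM of at least 1 in at least 3 of the 6 libraries, of which 12024 were protein coding. Differences were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), CXCL3 minus control, two-sided, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. A log2 fold change on this scale understates the change of genes with low TPM. The prior of the variance had 3.53 degrees of freedom. Values are given as mean ± SD of 3 libraries in TPM, and fold changes with their standard error. Exact permutation of 3 against 3 libraries cannot go below p = 0.1, so single genes were not tested that way. No columns of the table were identical.

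Gene lists of fibroblast and stress responses, technical lists and cell type markers were written from textbook knowledge before the data were examined, as were the tests and the settings. Lists with at least 5 genes kept were tested with camera in limma, with a preset correlation of 0.01 between genes and adjustment over the lists of a kind: 24 response lists, 3 technical lists and 2 cell type lists. Camera asks whether a list's genes stand apart from all other genes. The list of MHC class II genes had 4 of 7 members kept, and 11 cell type lists had fewer than 5, so these are given as levels only. Each list was also tested with an estimated correlation and with fry, which asks whether the list's own genes move one way.

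The genes named follow a rule set beforehand. It takes 17 genes of chemokine signalling and fibroblast state whatever their result. It takes up to 12 genes with the largest fold change in each direction among those that passed with a mean TPM of at least 5, groups that did not overlap and a protein-coding type, and, where fewer than 12 passed, up to 5 further genes with the smallest p. It takes up to 4 members of each response list with the smallest p among those that passed over the list alone and up to 2 in the other direction, and the 5 genes with the highest mean TPM. The other genes that passed over all genes and are named (Ms4a7, Pde11a and Gm42031) and the further list members named (Actg2, Cnn1, Cald1, Vcl, Emilin1 and the cell type markers) were chosen after their values were seen. The result of 1 gene is not reported here.

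The fit was repeated with other pseudocounts (0.1 and 5), no filter and a filter of 5 TPM, median-of-ratios scaling, quantile normalization, removal of mitochondrially encoded genes, eBayes without trend and with robust estimation, library weights from arrayWeights, the replicate number as a block, protein-coding genes alone, stricter thresholds and leaving out each library. After the data were seen, 3 were added: removal of each library's trend with transcript length and GC content by loess, the same with library weights, and a fit without controls 2 and 3. The fit was tested on simulated data with the spread of the real libraries over 13139 genes, in 10 runs with 200 genes changed. It called 27.9% of genes changed 1.5-fold, 67.8% of those changed 2-fold and 93.9% of those changed 4-fold, with 6.2 false calls in a run on average, and camera called the changed list in 10 of 10 runs. The simulated genes varied independently and with the same spread in both groups. In the real libraries genes shifted together with transcript length and the controls varied more. The simulated rates, camera's included, need not hold there. Figures were drawn with matplotlib 3.10.9.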

Results

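Gene expression was measured by RNA sequencing in primary mouse fibroblasts that had been kept for 48 h with the chemokine CXCL3 or under control conditions. CXCL3 is a secreted chemokine of the CXC family whose known receptor is CXCR2. Each group held 3 libraries from cells of mice aged 6 weeks, so that the series rests on 6 libraries. The labels give neither the organ the fibroblasts came from nor the dose of CXCL3. The series title places the comparison in a study of CXCL3, myofibroblasts and pancreatic cancer spread, and its question is how fibroblasts respond to CXCL3. Between 19493 and 20270 genes had a TPM above 0 in a library. TPM keeps no trace of the number of reads, so the depth of each library is unknown and no value is given a counting interval. The labels do not say that the replicates were separate cultures or animals, and the p-values then measure the spread between these libraries, which can be technical.

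The control libraries differed among themselves more than the CXCL3 libraries did. The median SD of a gene's log2 value was 0.20 among the 3 controls and 0.086 among the 3 CXCL3 libraries. The first principal component held 52.9% of the variance and set control 2 (36.6) and control 3 (26.6) apart from control 1 (-19.2), which lay beside CXCL3 libraries 1, 2 and 3 (-18.7, -16 and -9.39). Transcript length followed the same division. Across genes, which are not independent replicates, the deviation of a library from the mean of all 6 had a Spearman correlation with transcript length of 0.45 in control 1, -0.50 in control 2, -0.48 in control 3, and 0.40, 0.37 and 0.20 in CXCL3 libraries 1, 2 and 3. The log2 fold change between the groups had a correlation of 0.45 with transcript length across genes. All libraries carry the same collection date, so no batch could be separated by the labels.

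**Figure D1:**
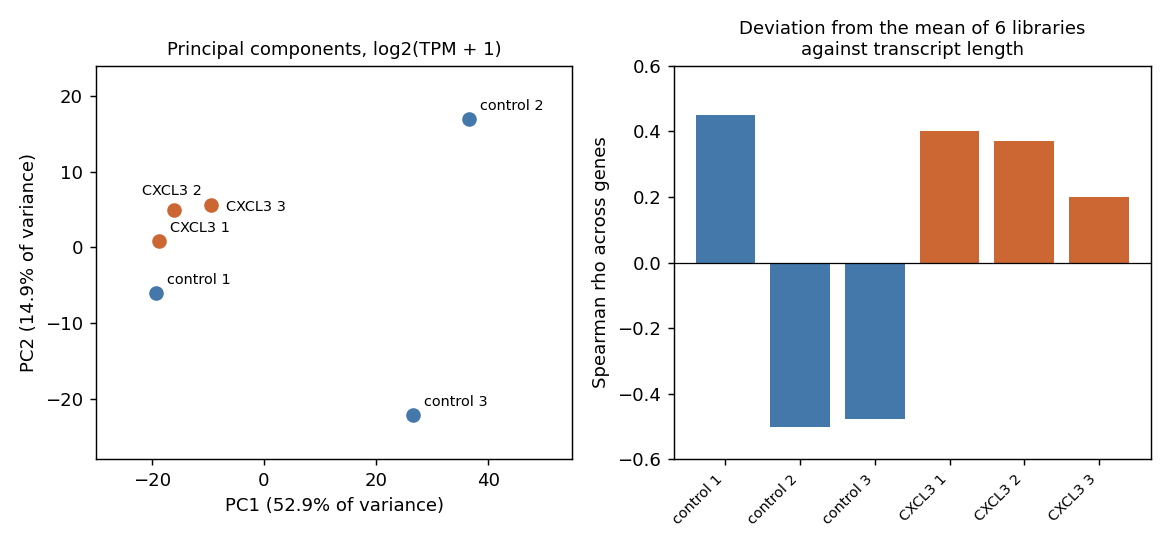
Left, the 6 libraries on the first and second principal components of log2(TPM + 1), with the share of variance on each axis; controls 2 and 3 lie at 36.6 and 26.6 on the first component and the other 4 libraries between -19.2 and -9.39. Right, bars give the Spearman correlation across genes between a library's deviation from the mean of the 6 libraries and transcript length, negative in controls 2 and 3 and positive in the other 4; blue is control and orange is CXCL3.

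Fibroblast cultures kept with CXCL3 had lower transcript levels of smooth muscle actin and of a major collagen than control cultures. The values are of whole cultures, in which macrophage markers were abundant too. Acta2, which encodes alpha smooth muscle actin, the usual marker of myofibroblasts, fell from 1082 ± 59.9 TPM in controls to 660.4 ± 8.02 TPM with CXCL3 (mean ± SD, n = 3 each; 1.64-fold lower; log2 fold change -0.71 ± 0.06 SE; limma, adjusted p = 0.0293). Tagln, which encodes the actin-binding protein transgelin, fell from 1172 ± 34.2 to 796.8 ± 3.21 TPM (log2 fold change -0.56 ± 0.06, adjusted p = 0.0293). Col3a1, the chain of type III collagen, fell from 407.5 ± 56.5 to 195.5 ± 7.91 TPM (-1.05 ± 0.11, adjusted p = 0.0293). All 3 kept their sign but lost their call without control 3 (adjusted p = 0.10 for Acta2, 0.129 for Tagln and 0.129 for Col3a1), and without any one CXCL3 library (0.175 to 0.239). All 3 also lost it with no filter and with eBayes without trend, and Acta2 and Tagln with median-of-ratios scaling. The annexin gene Anxa8 rose from 17.0 ± 0.98 to 32.0 ± 1.20 TPM and the quinone reductase gene Nqo1 from 130.9 ± 8.92 to 209.2 ± 6.27 TPM. The interleukin-1 receptor antagonist gene Il1rn rose from 52.7 ± 5.13 to 88.9 ± 1.35 TPM and Dlgap5, a gene of the mitotic spindle, from 5.74 ± 0.76 to 13.1 ± 1.1 TPM. The adjusted p of these 4 lay between 0.0293 for Anxa8 and Nqo1 and 0.0493 for Dlgap5. All 4 lost their call with no filter, with median-of-ratios scaling, with eBayes without trend, without control 3 (0.129 for Anxa8, Nqo1 and Il1rn, 0.215 for Dlgap5) and without any one CXCL3 library (0.175 to 0.352). Anxa8 and Dlgap5 also lost it without control 2 (0.0946 and 0.113). Every direction rests on the group labels, because the table holds no gene whose level tells treated from untreated cells independently.

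In all, 21 of the 13139 genes tested passed an adjusted p of 0.05, 4 higher and 17 lower with CXCL3, and 5 of the 21 changed at least 2-fold. The 3 libraries of one group lay wholly above or below the other 3 for all 21, against 2263 genes of all those tested (17.2%, where chance gives 10%). A gene with overlapping groups can hardly pass here, so the separation of the 21 follows from how they were chosen. An unadjusted p under 0.05 was found for 1522 genes, where 657 are expected by chance. This excess is not specific to CXCL3, since setting control 1 and CXCL3 libraries 1 and 2 against the other 3 libraries gave 3334 such genes. Others of the 17 that fell encode the plasma proteins haptoglobin (Hp, 321.8 ± 12.1 to 194.5 ± 2.22 TPM, log2 fold change -0.72) and transferrin (Trf, 610.7 ± 74.5 to 364.2 ± 11.4 TPM, -0.74). The genes of the complement C1 inhibitor (Serping1, 248.2 ± 26.7 to 137.5 ± 2.45 TPM, -0.84) and of apolipoprotein E (Apoe, 910.8 ± 89.9 to 522.8 ± 8.14 TPM, -0.80) fell. The complement subunit gene C1qa (288.9 ± 38.6 to 167.1 ± 5.46 TPM, -0.78) and the matricellular gene Ccn5 (11.7 ± 0.68 to 4.93 ± 0.38 TPM, -1.10) fell as well. Rcn3, of a calcium-binding protein of the endoplasmic reticulum, fell from 419.6 ± 34.2 to 277.0 ± 4.79 TPM, and Dpm1, of dolichol phosphate mannose synthase, from 59.0 ± 3.68 to 36.5 ± 2.31 TPM. The protease inhibitor gene Ctla2a fell from 328.8 ± 36.2 to 182.4 ± 10.8 TPM and Ms4a7 from 173.0 ± 13.1 to 114.5 ± 3.54 TPM. The predicted gene Gm11007 fell from 9.66 ± 4.10 to 1.23 ± 0.29 TPM and the long non-coding RNA Gm42031 from 28.6 ± 1.76 to 14.2 ± 1.03 TPM. The phosphodiesterase gene Pde11a was listed at 2.28, 1.73 and 2.52 TPM in controls 1, 2 and 3, and at 0.04, 0 and 0 TPM in CXCL3 libraries 1, 2 and 3. All 17 lower genes lost their call with no filter, without control 3 and without any one CXCL3 library. C1qa, Trf, Dpm1, Rcn3 and Ms4a7 passed narrowly (limma, adjusted p = 0.0493 each) and lost it with a pseudocount of 0.1 too (0.0516 to 0.0542). Trf, Dpm1 and Ms4a7 also lost it with the length and GC trend removed (0.0751, 0.0751 and 0.078).

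Of the 21 genes, 9 overlap another annotated gene, and the counting was not stated to use strand. Trf and Dpm1 overlap Gm20425 and Gm20716 on the same strand (mean 6.99 and 25.2 TPM), and Tagln overlaps the antisense gene Gm48529 (mean 5.48 TPM). Ctla2a has the close paralog Ctla2b. The split of reads between these genes is uncertain. On the mouse genome build GRCm38, Acta2 (ENSMUSG00000035783) lies on chromosome 19 from 34241090 to 34255590, Tagln (ENSMUSG00000032085) on chromosome 9 from 45929619 to 45936058, and Col3a1 on chromosome 1 from 45311538 to 45349706. The genes with the smallest unadjusted p that were higher without passing were Upp1 (40.6 ± 3.78 to 63.7 ± 1.70 TPM, adjusted p = 0.0752) and Atf3 (26.0 ± 2.00 to 40.9 ± 1.37 TPM, 0.0757). Next came Id1 (62.0 ± 7.0 to 98.3 ± 5.70 TPM, 0.10), Plin2 (338.6 ± 8.0 to 431.2 ± 6.10 TPM, 0.110) and Gphn (1778 ± 111 to 2467 ± 155 TPM, 0.110). The count of changed genes moved with the libraries used: limma called 4254 genes without control 1 (3312 higher, 942 lower), 10 without control 2, 1 without CXCL3 library 3, and 0 without control 3, CXCL3 library 1 or CXCL3 library 2. Without these, in the same order, 875, 765 and 799 genes had an unadjusted p under 0.05. Library weights gave 1446 calls, 1046 higher and 400 lower, so the balance of directions is not stable. Median-of-ratios scaling left 4 calls, 0 higher and 4 lower. Removal of each library's trend with transcript length and GC content gave 43 calls, 13 higher and 30 lower. All 21 genes kept their sign in each of these settings, which for a library left out follows from groups that did not overlap.

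**Figure D2:**
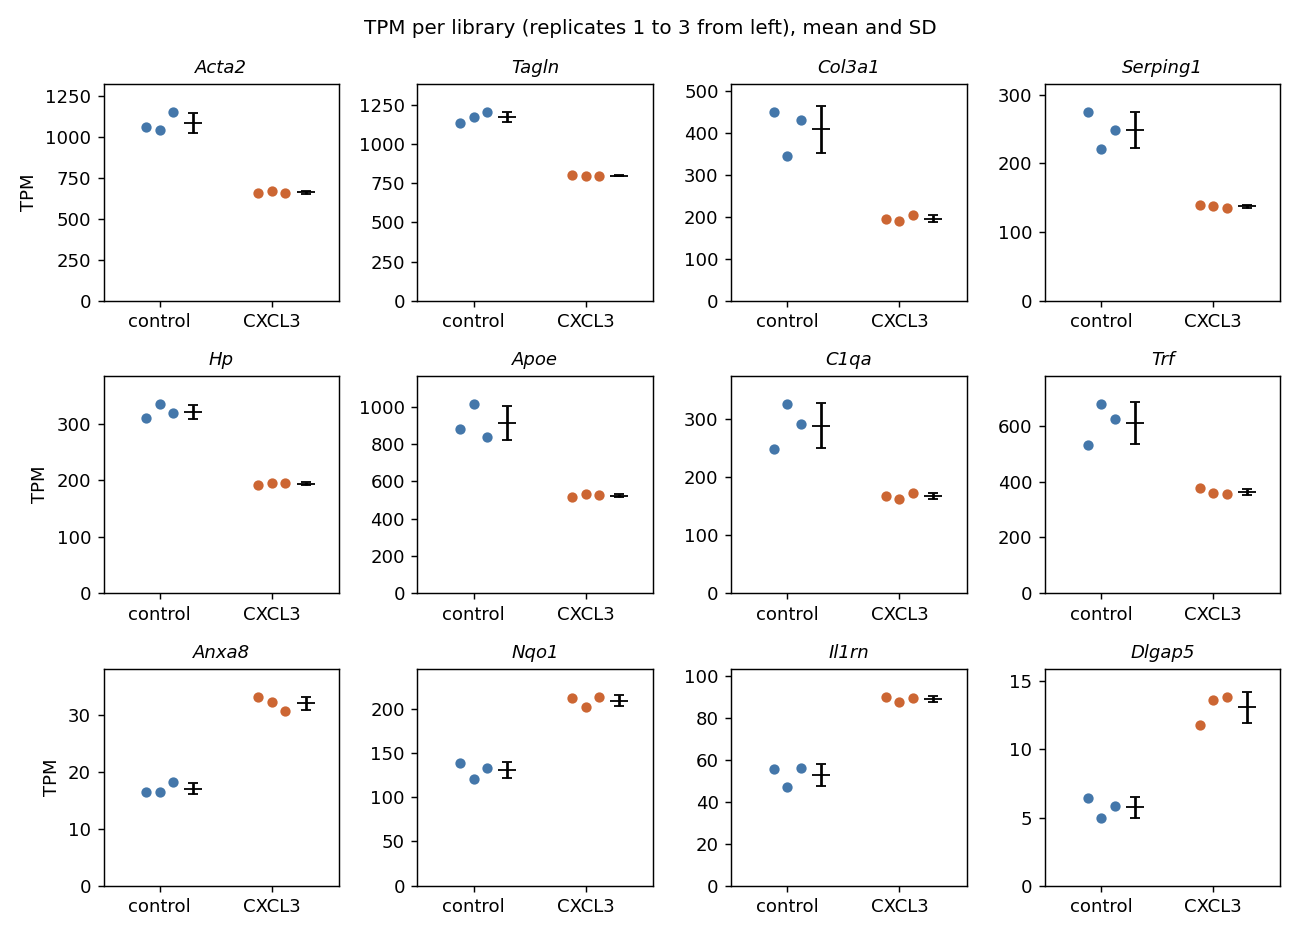
TPM of 12 of the changed genes in each library (blue, control; orange, CXCL3; replicates 1 to 3 from left), with the mean and SD of the 3 libraries in black; each vertical axis starts at 0. Acta2, Tagln, Col3a1, Serping1, Hp, Apoe, C1qa and Trf were lower and Anxa8, Nqo1, Il1rn and Dlgap5 higher in all 3 CXCL3 libraries than in any control.

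Myofibroblast contractile genes were lower with CXCL3 as a list (15 members measured; camera, adjusted p = 8.66e-04), but not with an estimated correlation between genes (adjusted p = 0.567). Acta2 and Tagln passed over all genes, and 6 members were lower when adjusted over the list alone, the other 4 being Actg2, Myl9, Tpm2 and Cnn1. Myl9, a myosin light chain gene, went from 197.3 ± 8.20 to 146.0 ± 3.00 TPM (log2 fold change -0.43, adjusted p = 0.0849 over all genes) and the tropomyosin gene Tpm2 from 517.4 ± 52.2 to 401.1 ± 2.95 TPM (-0.36, 0.196). The other 9 members did not pass, and 6 of them had a positive fold change, among them the actin-linked genes Cald1 (438.7 ± 145 to 574.0 ± 23.3 TPM) and Vcl (39.3 ± 18.7 to 58.3 ± 3.43 TPM). Fibrillar collagens and collagen-processing genes were lower as a list (22 members, adjusted p = 0.000112; adjusted p = 0.621 with an estimated correlation). Col3a1 passed over all genes, and 2 were lower when adjusted over the list alone, Col3a1 and the procollagen processing enhancer gene Pcolce (48.2 ± 2.85 to 33.5 ± 2.45 TPM). Matrix glycoproteins and proteoglycans were lower as a list (17 members, 8 positive and 9 negative, adjusted p = 0.0139; adjusted p = 0.784 with an estimated correlation). No member passed over all genes and 5 were lower when adjusted over the list alone. These were Tgfbi (50.02 ± 4.36 to 33.9 ± 0.70 TPM), Sparc (2227 ± 167 to 1672 ± 19.1 TPM), Postn, which encodes periostin (50.4 ± 5.85 to 33.2 ± 0.73 TPM), Mfap5 (114.9 ± 7.16 to 87.5 ± 7.55 TPM) and Emilin1. The 3 lists did not pass by fry (0.153, 0.392 and 0.461) or without control 1 (0.146, 0.130 and 0.458). The matrix glycoprotein list was also lost with quantile normalization (0.0671) and with library weights (0.184). The median log2 fold change of the 3 lists was -0.11, -0.20 and -0.01, where that of all genes was 0.07. Controls 2 and 3, which stood apart, hold 2 of the 3 control values behind each member.

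The list of mitotic genes was higher with CXCL3 (22 members, adjusted p = 6.64e-07; adjusted p = 0.567 with an estimated correlation), with 21 positive fold changes and a median of 0.42. No member passed over all genes, and 8 were higher when adjusted over the list alone. Among these were the topoisomerase gene Top2a (24.8 ± 2.40 to 35.8 ± 2.00 TPM, log2 fold change 0.51), Cdc20, an activator of the anaphase-promoting complex (12.4 ± 1.73 to 19.5 ± 1.72 TPM, 0.62), Birc5 (19.4 ± 1.00 to 26.0 ± 1.34 TPM, 0.40) and the spindle gene Tpx2 (12.3 ± 1.34 to 17.7 ± 0.90 TPM, 0.50). DNA replication genes were higher as a list (23 members, 21 positive, median 0.26, adjusted p = 3.98e-04; adjusted p = 0.567 with an estimated correlation), with 0 members past the threshold over all genes and 0 when adjusted over the list alone. By fry neither list passed (adjusted p = 0.0884 and 0.125). Replication-dependent histones, kept as a technical list, were lower (11 members, adjusted p = 5.38e-04; adjusted p = 0.0513 with an estimated correlation), with 3 lower when adjusted over the list alone.

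The list of inflammatory cytokines and chemokines was lower against all other genes (22 members, camera, adjusted p = 0.0339, and 0.567 with an estimated correlation). Its members were 9 positive and 13 negative, with a median log2 fold change of -0.04, where that of all genes was 0.07. No member passed over all genes. Adjusted over the list alone, 3 were lower and 1 higher. The acute-phase gene Saa3 (14610 ± 2190 to 9891 ± 69.4 TPM, log2 fold change -0.55), Cxcl12 (47.3 ± 3.23 to 34.8 ± 1.42 TPM, -0.43) and Ccl7 (1636 ± 242 to 1227 ± 12.1 TPM, -0.40) lay below controls, and Csf3 (43.2 ± 2.26 to 53.9 ± 3.78 TPM, 0.31) above. This call was lost in 11 of 23 alternative settings. The transcript of CXCL3 itself, Cxcl3, was at 175.8 ± 13.3 TPM in controls and 169.7 ± 3.07 TPM with CXCL3 (adjusted p = 0.75), and did not differ by more than the spread between libraries. The related ligands Cxcl1 (469.2 ± 34.0 and 412.9 ± 13.5 TPM, adjusted p = 0.416), Cxcl2 (211.9 ± 13.8 and 216.1 ± 4.15 TPM, 0.833) and Cxcl5 (474.3 ± 43.3 and 448.0 ± 9.50 TPM, 0.632) did not pass either. The receptor gene Cxcr2 was at 0.02 to 0.12 TPM across the 6 libraries and Cxcr1 at 0 to 0.07 TPM, both below the filter and not tested. Among other chemokine receptors, Cxcr4 was at 31.3 ± 3.28 and 23.5 ± 1.93 TPM (adjusted p = 0.290), the scavenging receptor Ackr3 at 8.57 ± 1.86 and 11.3 ± 0.38 TPM (0.426) and Ackr1 at 2.80 ± 0.25 and 2.00 ± 0.54 TPM (0.457). Without control 1, Cxcl5, Cxcr4 and Ackr3 passed (adjusted p = 0.0369, 0.0479 and 0.0136), and Ackr3 also passed with library weights (0.0485). Il33 (27.3 ± 4.15 and 23.2 ± 0.30 TPM, adjusted p = 0.478), the gene of its receptor Il1rl1 (3.70 ± 0.46 and 4.33 ± 1.39 TPM, 0.708) and Cd9 (269.4 ± 15.3 and 262.8 ± 3.93 TPM, 0.800) did not pass.

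Of the lists on metabolism and defence, 5 more passed with the preset correlation. Cholesterol synthesis genes were lower (21 members, 18 negative, adjusted p = 8.66e-04; adjusted p = 0.567 with an estimated correlation), with Msmo1 (29.6 ± 0.95 to 21.1 ± 1.40 TPM) lower when adjusted over the list alone. Lysosomal genes were lower (18 members, camera, adjusted p = 0.00956, and 0.583 with an estimated correlation), with 6 positive and 12 negative and a median log2 fold change of -0.04. Ctsd, which encodes cathepsin D (5937 ± 58.2 to 4842 ± 74.2 TPM), was lower when adjusted over the list alone. Markers of macrophages, which are rich in lysosomes, were lower as a list too (adjusted p = 0.00536; adjusted p = 0.0655 with an estimated correlation). Nuclear-encoded respiratory chain genes were lower (25 members, camera, adjusted p = 0.00733, and 0.567 with an estimated correlation), with 0 members past either threshold. Of these members 9 were positive and 16 negative, with a median of -0.09. Adipogenic and lipid storage genes were higher (8 of 14 members measured, adjusted p = 0.0266; adjusted p = 0.567 with an estimated correlation), with 3 higher when adjusted over the list alone. These were the lipid droplet gene Plin2, the lipoprotein lipase gene Lpl (4.55 ± 0.52 to 7.29 ± 0.22 TPM) and the fatty acid transporter gene Cd36 (180.0 ± 17.9 to 220.6 ± 3.45 TPM). Interferon-stimulated genes were higher (23 members, 21 positive, adjusted p = 0.0266; adjusted p = 0.583 with an estimated correlation), with 0 members past either threshold. By fry none of the 5 passed (adjusted p in this order 0.278, 0.278, 0.392, 0.0977 and 0.153). Removal of the trend with transcript length and GC content ended the call of the respiratory chain list (adjusted p = 0.69, and 0.605 with library weights) and of the lipid list (0.213 and 0.252). Median-of-ratios scaling (0.243) and library weights alone (0.116) also ended that of the lipid list, and library weights (0.184) and a filter of 5 TPM (0.0691) that of the interferon list. Without control 1 the lysosome list (adjusted p = 0.161), the lipid list (0.24) and the interferon list (0.24) were lost. The interferon list was also lost without CXCL3 library 2 (0.077), and the respiratory chain list without control 2 (0.28). Quantile normalization ended the calls of 4 of the 5, all but cholesterol synthesis.

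The other 13 response lists did not pass. Their adjusted p was 0.0885 for growth factors and their receptors and 0.315 to 0.327 for oxidative stress, heat shock, MHC class I and the unfolded protein response. It was 0.564 to 0.840 for TGF-beta targets, YAP targets, NF-kappaB targets, p53 targets, glycolysis, hypoxia, immediate early genes and matrix proteases. The technical lists of ribosomal proteins and of mitochondrially encoded genes had an adjusted p of 0.306 each. Within these lists, Nqo1 passed over all genes in the oxidative stress list. Adjusted over their own list alone, Hsp90aa1 (326.9 ± 47.3 to 461.1 ± 15.3 TPM) and Atf3 were higher. The growth factor list held Igfbp4 (130 ± 17.3 to 180.7 ± 6.17 TPM), Fgf7 (29.1 ± 2.76 to 38.0 ± 2.03 TPM) and Ereg (66.2 ± 9.77 to 88.7 ± 3.46 TPM) as higher when adjusted over it alone. In the same way Tgfbi was lower among TGF-beta targets, and the protease list held Timp1 (5907 ± 500 to 4720 ± 61.6 TPM) and Mmp14 (670.5 ± 51.7 to 549.6 ± 7.39 TPM) as lower and Mmp13 (10.1 ± 1.35 to 16.03 ± 1.58 TPM) as higher. The lists of matrix proteases, NF-kappaB targets, hypoxia targets and the unfolded protein response were tested as lower although their median fold changes were positive (0.05, 0.01, 0.01 and 0.04), since the test sets a list against all other genes. Without control 3 and without CXCL3 library 1 the growth factor list passed (adjusted p = 0.0325 and 0.038).

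**Figure D3:**
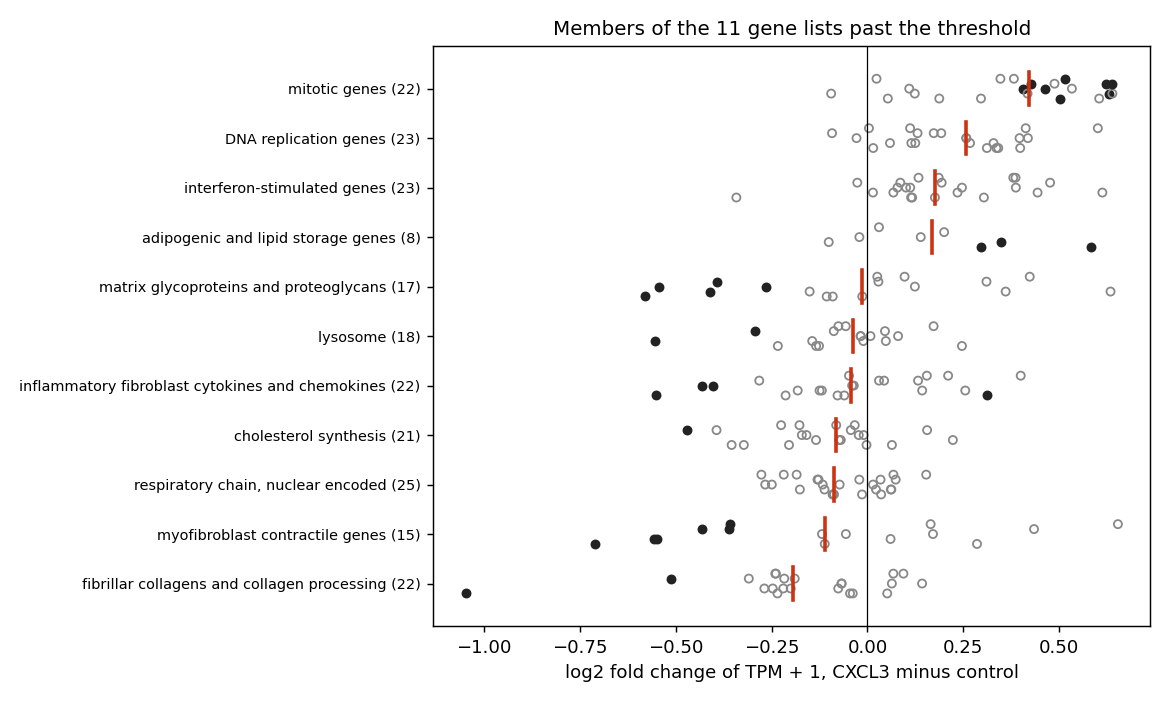
Log2 fold change (CXCL3 minus control, on TPM + 1) of each measured member of the 11 gene lists past the threshold, with the number of members in brackets. Filled points pass when adjusted over their list alone, open points do not, and the red line is the list's median, from -0.20 for fibrillar collagens to 0.42 for mitotic genes.

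Both fibroblast and macrophage markers were abundant in the libraries, all of which are labelled as primary fibroblasts. Of 20 fibroblast markers, 15 had a mean of at least 1 TPM, among them Fbln2 (3934 ± 577 TPM in controls, 4177 ± 118 with CXCL3), Vim (1563 ± 145 and 1689 ± 19.0 TPM) and Col1a1 (721.0 ± 219 and 603.5 ± 33.4 TPM). The receptor genes Pdgfra (12.2 ± 3.72 and 13.6 ± 0.15 TPM, adjusted p = 0.643) and Pdgfrb (22.1 ± 7.18 and 21.9 ± 1.6 TPM, 0.942) did not pass, and Fap lay at 0.16 to 0.54 TPM, below the filter. Without control 1, Pdgfra passed as higher (log2 fold change 0.40, adjusted p = 0.0142). All 15 macrophage markers had a mean of at least 1 TPM and 11 of at least 100 TPM. The lysozyme gene Lyz2 (14620 ± 1460 in controls, 13190 ± 65.7 TPM with CXCL3) was among the 5 genes with the highest mean TPM. The others were mt-Atp8 (24390 ± 3590 and 31660 ± 463 TPM), Fth1 (24830 ± 1710 and 24160 ± 551 TPM), mt-Co1 (17370 ± 1830 and 19600 ± 243 TPM) and the pseudogene Gm28661 (14540 ± 1330 and 14840 ± 352 TPM). The genes of the F4/80 antigen, Adgre1 (438.8 ± 72.3 and 449.6 ± 12.1 TPM), of Cd68 (295.0 ± 21.6 and 283.7 ± 6.80 TPM) and of the colony-stimulating factor receptor, Csf1r (94.7 ± 13.6 and 100.7 ± 1.86 TPM), did not pass.

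Macrophage markers were lower with CXCL3 as a list (15 members, camera, adjusted p = 0.00536 over the 2 cell type lists that could be tested, 0.0655 with an estimated correlation, and 0.00421 by fry). Of the 15, 6 were positive and 9 negative, with a median log2 fold change of -0.07. C1qa passed over all genes. Adjusted over the list alone, C1qb (300.4 ± 36.5 to 223.7 ± 3.79 TPM), C1qc (227.2 ± 15.5 to 165.8 ± 4.54 TPM) and the Fc receptor chain gene Fcer1g (583.3 ± 71.0 to 423.8 ± 2.69 TPM) were lower too, and the mannose receptor gene Mrc1 (11.5 ± 1.80 to 17.0 ± 1.02 TPM) was higher. Fibroblast markers did not pass as a list (adjusted p = 0.542), with S100a4 (609.6 ± 74.4 to 770.2 ± 24.3 TPM) and Ly6a higher and Mfap5 lower when adjusted over the list alone. Markers of the other cell types had at most 4 members each at 1 TPM or more. The highest of these were the neutrophil gene S100a8 (600.7 TPM in controls, 555.4 with CXCL3), Wt1 among mesothelial markers (28.2 and 30.3) and Ndufa4l2 among pericyte markers (28.6 and 22.7). Next were Cela1 among acinar markers (26.1 and 24.7), Esam among endothelial markers (14.3 and 16.3), Spint1 among epithelial markers (11.1 and 9.03), Ivl among keratinocyte markers (10.0 and 11.8) and Acta1 among skeletal muscle markers (6.46 and 3.17). Lymphocyte, Schwann cell and red blood cell markers reached at most 1.47 TPM as a group mean.

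**Figure D4:**
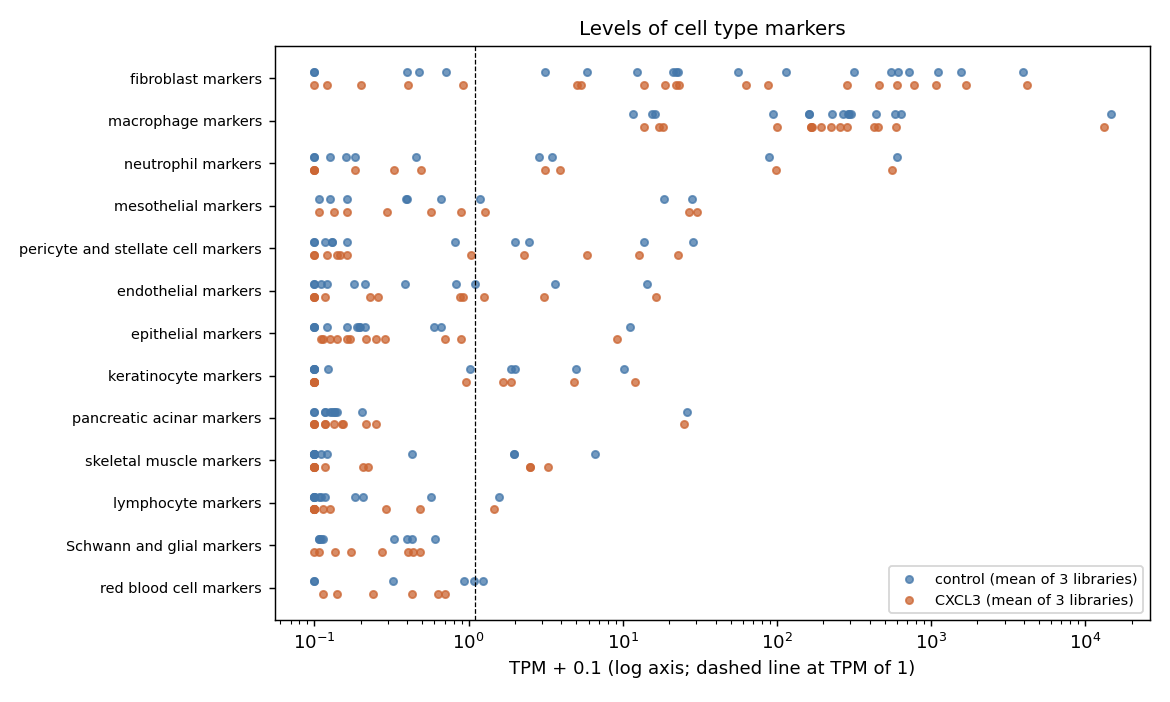
Mean TPM + 0.1 of each marker gene (log axis) in the 3 control libraries (blue) and the 3 CXCL3 libraries (orange), by cell type list, with a dashed line at 1 TPM. All 15 macrophage markers and 15 of 20 fibroblast markers lie above the line, and at most 4 markers of any other cell type do.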

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

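All 21 genes kept the sign of their fold change in the settings that tested them. Their groups did not overlap, so leaving out a library could not turn a sign, and the kept signs do not measure stability. With no filter, no gene passed (0 higher, 0 lower; limma, 1928 with an unadjusted p under 0.05 of 25130 tested). Median-of-ratios scaling left 4 (0 higher, 4 lower), eBayes without trend 1 (0 higher, 1 lower), an adjusted p of 0.01 left 0 in either direction and a 2-fold minimum 5 (1 higher, 4 lower). Without mitochondrially encoded genes 11 were lower. Library weights gave 1446 (1046 higher, 400 lower). The alternatives chosen after seeing the data gave 43 with the length and GC trend removed (13 higher, 30 lower; 18 of the 21 shared), 471 with library weights added (190 higher, 281 lower) and 84 without controls 2 and 3 (32 higher, 52 lower; 18 shared), where the lone control is assumed to vary like the CXCL3 libraries. Leaving out each library in turn gave 0 to 4254 genes, 0 to 3312 higher and 0 to 942 lower, the highest without control 1. The remaining settings gave 14 to 23 genes. Part of the loss without a library comes from fewer samples, and the cause was not tested otherwise. The replicate numbers did not pair the libraries: deviations from the group means of same-numbered libraries correlated at 0.12, -0.011 and 0.077, and control 2 correlated best with CXCL3 library 3 (0.13). With the number as a block 12 genes passed (9 lower), 9 of them among the 21. Acta2 lost its call with no filter (log2 fold change -0.709, adjusted p = 0.107), median-of-ratios scaling (-0.794, 0.112), eBayes without trend (-0.709, 0.115), without control 3 and without any one CXCL3 library. Over the libraries left out it lay between -0.738 and -0.664, and its adjusted p over all settings between 0.00387 and 0.227. The 11 lists past the threshold fell to 5 with quantile normalization, to 0 with an estimated correlation and to 0 with fry, and ranged from 4 to 12 with a library left out. Without controls 2 and 3, TGF-beta targets (adjusted p = 0.00133) and YAP targets (0.00224) passed as lower instead of lying higher, and respiratory chain genes lay higher (0.0916). Matrix proteases (0.0137) and hypoxia targets (0.0356) passed as lower in that setting. Some genes that did not pass with all 6 libraries changed sign, the cause not being tested. Pdgfrb lay at -0.048 with median-of-ratios scaling, -0.053 with quantile normalization, -0.163 with the trend removed, -0.129 with weights added, -0.450 without controls 2 and 3, and -0.129 to 0.273 with a library left out. Pdgfra lay at -0.037, -0.019 and -0.259 in the 3 added settings, and passed as higher without control 1 (0.401, adjusted p = 0.0142). Il1rl1 lay at -0.011 and -0.061 with the trend removed without and with weights, and at -0.05 to 0.264 with a library left out. Cd9 lay at 0.020 with quantile normalization, 0.023 with the trend removed, 0.039 without controls 2 and 3, and -0.071 to 0.009 with a library left out. Cxcl2 lay at -0.054 with median-of-ratios scaling, -0.007 with library weights, 0.000 with the trend removed and weights, and -0.013 to 0.079 with a library left out. Gm28661 lay at -0.051 with median-of-ratios scaling, -0.020 with library weights, and -0.044 to 0.082 with a library left out. Without controls 2 and 3, Cxcl3 lay at 0.044, Cxcl5 at 0.078 and Fth1 at 0.073, while Cxcl5 passed as lower without control 1 (-0.156, adjusted p = 0.0369), and with a library left out Cxcl3 at -0.094 to 0.011 and Fth1 at -0.092 to 0.006. The median log2 fold change of all genes was 0.07, -0.00478 with median-of-ratios scaling, 0.11 with library weights and 0.14 without control 1. What the depth of the libraries limits is unknown, since TPM keeps none.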

Other observations

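Removal of each library's trend with transcript length and GC content, a setting chosen after the data were seen, called 25 further genes, 9 higher and 16 lower with CXCL3. The 16 were not tested as a group, and they also include Hist1h1c, Gpr84, Pld4, Dio3, Cyp4f18 and Lpcat2. Matrix genes among them were Tgfbi (log2 fold change -0.60 after removal, limma, adjusted p = 0.016), Postn (-0.76, 0.0161), Sparc (-0.41, 0.0345), Col5a1 (-0.56, 0.0318) and Col1a2 (-0.44, 0.0437). Col5a1 lay at 82.8 ± 24.9 TPM in controls and 66.7 ± 1.98 with CXCL3 and Col1a2 at 553.3 ± 140 and 459.3 ± 17.1 TPM (SD, n = 3). The 2 groups overlapped for both, and neither passed before removal (adjusted p = 0.511 and 0.503). The higher ones included the transcription factor genes Atf3 (0.66, limma, adjusted p = 0.0287) and Gata2 (0.73, 0.0395). Also higher were Id1 (0.73, 0.0302), the histone variant gene H2afz (0.37, 0.04) and the lipid droplet gene Plin2 (0.38, 0.0345). These genes were named after their values were seen.

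In the following, the tests of the length and GC trend and of marker levels for the 2 sets of lower genes, and that of Acta2 and Tagln in control 1, were chosen after the result was seen. So was the test of a larger share of TPM taken by abundant genes. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 21 genes and the highest of the others 1. For genes in one direction the real split gave 17 lower and 4 higher and the highest other 1, and for gene lists it gave 11 and the highest other 10. The split with 10 lists set control 1, control 3 and CXCL3 library 2 against the rest. Calls of lists by camera with the preset correlation thus also arose where the groups were mixed, and their p-values need not hold in these libraries. With 10 splits no share under 0.05 can be reached. The split of control 1 and CXCL3 libraries 1 and 2 from the other 3 gave 3334 genes with an unadjusted p under 0.05 by limma, against 1522 for the real one, which points to a structure of the libraries apart from treatment.

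Controls 2 and 3 stood apart from control 1 and from the CXCL3 libraries. Their shift with transcript length and GC content is not the whole of it: the median SD among controls was 2.36 times that among CXCL3 libraries before removal of the trend and 1.81 times after it. A CXCL3-treated culture under the label of control 1 was tested over the 120 genes that differed at least 2-fold between controls 2 and 3 and the CXCL3 libraries after removal, where control 1 had a median position of 0.0393 between the CXCL3 mean at 0 and the mean of controls 2 and 3 at 1. That value lay in the range set beforehand for a wrong label. It decides nothing, because these genes were chosen where controls 2 and 3 stand apart. On a like scale in TPM, without removal of the trend, control 1 lay at 0.865 for the lower of Acta2 and Tagln. For each of them it lay at least 49.3 SD of the CXCL3 libraries above their mean, an SD that was small. With control 1 as the only control, the log2 fold change was -0.676 for Acta2 and -0.512 for Tagln. For Acta2 and Tagln, control 1 thus lay near the other controls and not at the CXCL3 level. Both genes were named beforehand, but this test was chosen after both had passed with all libraries. A gene with control 1 at the CXCL3 level could hardly pass so, and the test does not decide on a wrong label. Both also passed without control 1 (limma, adjusted p = 0.00387 and 0.00336), a result that a wrong label would give too. A wrong label of control 1 stays open. So do differences in culture, depth or library preparation between the controls, which could not be tested with these labels.

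C1qa, C1qb, C1qc and Fcer1g were lower with CXCL3 in cultures with abundant macrophage markers. A smaller share of macrophages would lower all 15 markers by about the median of these 4 (-0.451). The median of the 15 was -0.071, with an SD of 0.333 between markers, 6 of them positive and 9 negative. The 4 were picked from the 15 because they were lower, so the gap follows in part from that choice and decides nothing. These fold changes also still held the length and GC trend. The list as a whole was lower (camera, adjusted p = 0.00536, and 0.0655 with an estimated correlation), so a smaller share of macrophages stays open. With the length and GC trend removed the median of the 4 was -0.380, so the trend as removed accounts for only part of their lower level. All 4 then passed over the list alone (limma, largest adjusted p = 0.00773), but they had been picked from that list. Over all genes only C1qa passed after removal (limma, adjusted p = 0.0325), and C1qc (0.0518), Fcer1g (0.0688) and C1qb (0.111) did not. A candidate explanation that also stays open is a change within the macrophage-like cells or in part of them, which these libraries of whole cultures cannot test.

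Acta2, Tagln and Col3a1 were lower with CXCL3. The values argue against the length and GC trend as the cause, as the median log2 fold change of the 3 was -0.709 before and -0.681 after removal and all 3 stayed past the threshold. Fewer fibroblasts would lower the 15 fibroblast markers measured alike, and their median was 0.032 with an SD of 0.271. That median still held the length and GC trend and was not taken again after removal, so it does not set fewer fibroblasts aside. A larger share of TPM taken by abundant genes in the CXCL3 libraries would lower all genes, and the median of all genes was 0.0702. Open candidates are a response of the cultures to CXCL3, fewer fibroblasts and a different mix of fibroblast states between cultures. Group labels exchanged as a whole may also account for the 3 genes, and no value here tells these apart. The gene of the known CXCL3 receptor, Cxcr2, lay at 0.02 to 0.12 TPM across the libraries.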
